A study of Mus musculus with 3 samples.

How the data were processed

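The series holds total RNA-seq of mouse primary cells labelled T-helper 1, in 1 group of 3 biological replicates with 1 library each. Replicate numbers were taken from the labels, and each file's sample from the deposit's record. The labels give a shared donor identifier and separate biosamples, and sex as not collected.

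Each deposited table holds raw counts of fragments per gene made by the authors with featureCounts 1.4.6-p4, per the file headers. The counting used paired fragments with both ends mapped, strand setting 1 (the first read on the gene's strand), exons joined by gene identifier and the GENCODE M13 annotation, per the file headers. The names in the counting command refer to STAR, to stranded paired-end reads and to 0 hours, per the file headers, and the assembly is mm10, per the labels. The aligner's version, read trimming and library kit were not given in the sources used here. The command holds no option to count multi-mapping fragments, so near-identical gene copies may be undercounted. Genes that overlap on the same strand are also uncertain, since a fragment that falls on both is not counted by default.

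With the strand setting used, a fragment counts for a gene only where its first read has the gene's strand. If a kit yields the opposite orientation, the counts of a gene come from fragments of the other strand. For this reason each gene was classed by its annotation as having exons that overlap exons of the other strand (8189 genes), as within 5 kb of an opposite-strand gene (15317 genes), or as having none within 5 kb (27094 genes), from the coordinates in the deposited tables with bedtools 2.31.1. This classification and every result that uses it were added after the data were seen. Coordinates came from the deposited tables, and symbols and biotypes from GENCODE M21 by gene identifier, which named 50376 of 50600 identifiers and left 224 without a name.

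TPM were computed here from the deposited counts and the deposited summed exon length. The design had assumed estimated counts and TPM from the authors, and the tables held counts and no TPM. Tests and summaries were therefore applied to the counts and to these TPM, and the alternative with posterior mean TPM was not run. Counts scaled to depth (CPM) used effective library sizes by the trimmed mean of M-values (TMM) in edgeR 4.0.16, with DESeq2 1.42.0 size factors as an alternative. The libraries held 3647366, 4305077 and 2510319 counts. At Cxcr3, 3 counts correspond to 0.921, 0.885 and 1.16 TPM in replicates 1, 2 and 3, and 3 counts served as the floor for a gene with 0 counts. PCR duplicates were not told apart, so intervals and floors cover counting error only.

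With 1 group, no test between conditions was possible. The 35 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists with at least 8 matched members (31 lists) were described by the median of the members' mean log2(TPM + 0.1), with its percentile among 10000 random lists of the same size. The background was 13092 protein-coding genes with at least 0.1 TPM in a library or listed. The Th1 program was compared with 4 other helper programs by a two-sided permutation test of the gene labels (100000 resamples) with Benjamini-Hochberg adjustment over the 4 contrasts. Gene pairs were compared as log2 ratios of TPM + 0.1 within each library, with an exact sign-flip test whose smallest p is 0.25, and where a gene had few counts as a ratio of summed counts per base with an exact Clopper-Pearson 95% interval. The design set genes under 3 counts at the floor and gave the ratio as a bound. After the ratios were seen, a direction was counted only where the higher gene had at least 3 counts in each library, which took the pairs with the first gene higher from 8 to 4. The contrast of the Th1 program with naive T markers was also added after the data were seen.

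Variation between libraries was tested per gene against counting error by a Poisson chi-square test (2 degrees of freedom) at a Benjamini-Hochberg adjusted p of 0.05, over 10662 genes kept by filterByExpr, with the common dispersion estimated in edgeR. It compares these libraries and not conditions. Genes whose log2(CPM + 0.5) differed by over 1 between libraries were counted among those with a mean CPM of at least 1. List shifts were medians of the members' deviations from their mean over the libraries, set against 10000 random lists matched on mean expression in 10 bins. On simulated counts with no change, 0.0956% of genes were called. Of 100 genes changed by 1.5-fold 44% were called, and of 100 changed by 3-fold 98%, in a step over 10662 genes. The list shift step placed 95% of unshifted simulated lists inside the central 95% and 100% of shifted lists above it. The simulated deviations did not depend on exon overlap, so this step was not tested for shifts that follow exon overlap. Of 200 simulated lists the level step placed 95.5% inside the central 95%, and 88.5% above it when raised 8-fold. The contrast test called 5% of 200 unshifted and 78.5% of 200 8-fold raised lists.

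The rule for named genes took the first member and up to 4 highest members of each list, every gene of a pair, the 10 highest protein-coding genes outside mitochondrial and ribosomal protein genes, the 10 most variable genes past the threshold, up to 3 members of a shifted list, and the cytokines and master regulators of the programs. Genes named for their position opposite another gene, and further list members, were chosen after their values were seen. Some genes that the rule takes, and some pairs and loci, are counted in the totals and not reported here by name. Alternatives were other pseudocounts, thresholds, scalings, filters and backgrounds, leaving out each replicate, and, added after the data were seen, genes without exon overlap and genes with no opposite-strand gene within 5 kb. The text files that accompany each table hold no measurement and were not used. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, in R 4.3.3, and with matplotlib 3.10.9 for figures.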

Results

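Total RNA-seq was performed on primary mouse cells (strain C57BL/6NJ) labelled T-helper 1, the CD4 T cell subset that makes interferon gamma. The series held 1 group with 3 libraries, labelled as biological replicates 1, 2 and 3 from separate biosamples with a shared donor identifier. No second group was analysed here, so every comparison was made between genes within a library or between the 3 libraries. The header of each count table carried a time of 0 hours. The libraries held 3647366, 4305077 and 2510319 counts in replicates 1, 2 and 3, over 50600 annotated genes of which 17971, 17855 and 15100 had a count above 0. Levels are length-scaled transcript abundances (TPM) computed from the deposited counts, given as mean ± SD over the 3 libraries, and coordinates are those of the deposited tables (mm10, GENCODE M13). P-values over libraries measure the spread between these 3 libraries, and intervals cover counting error only.

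The most counted features lay opposite other annotated genes. These features were singled out after their values were seen. CT010467.1, an rRNA feature on chromosome 17 (39846353 to 39848827, minus strand) opposite Gm42418, held 202900, 82019 and 70696 counts in replicates 1, 2 and 3, against 9519, 6053 and 1041 for Gm42418. Gm11175, which shares 877 exonic bases with the transcription factor gene Jund on the other strand, held 6741, 8129 and 6126 counts, and Jund 396, 671 and 332. The mitochondrial gene mt-Nd6, the single light-strand protein gene, held 20191, 20392 and 21040 counts over 519 bases, against 9015, 14727 and 2276 for mt-Co1 over 1545 bases. Of the 20 features with the largest summed counts, 19 had exons that overlapped an exon of the other strand.

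Across the annotation, 8189 genes had such an exon overlap, and they held 63.1%, 53.8% and 76.5% of the counts of replicates 1, 2 and 3. Among features of at least 200 bases with 60 or more counts over both genes of the locus, in 204 cases a feature lay with at least 90% of its exonic bases inside the exons of a single gene of the other strand. The inner feature had more counts per base than the gene around it in 165, 160 and 165 of these 204 cases in replicates 1, 2 and 3, with median ratios of 25.5, 18.03 and 54.0 where both had counts. A level of a gene with exon overlap may hold fragments from the other strand's locus, and the overlap is stated below beside such genes. Absence of overlap does not clear a gene of this limit. Genes with no opposite-strand gene within 5 kb held 15.4%, 19.9% and 9.05% of the counts of replicates 1, 2 and 3. If the counting strand was opposite to the library's, these counts too would come from fragments of the other strand.

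**Figure D1:**
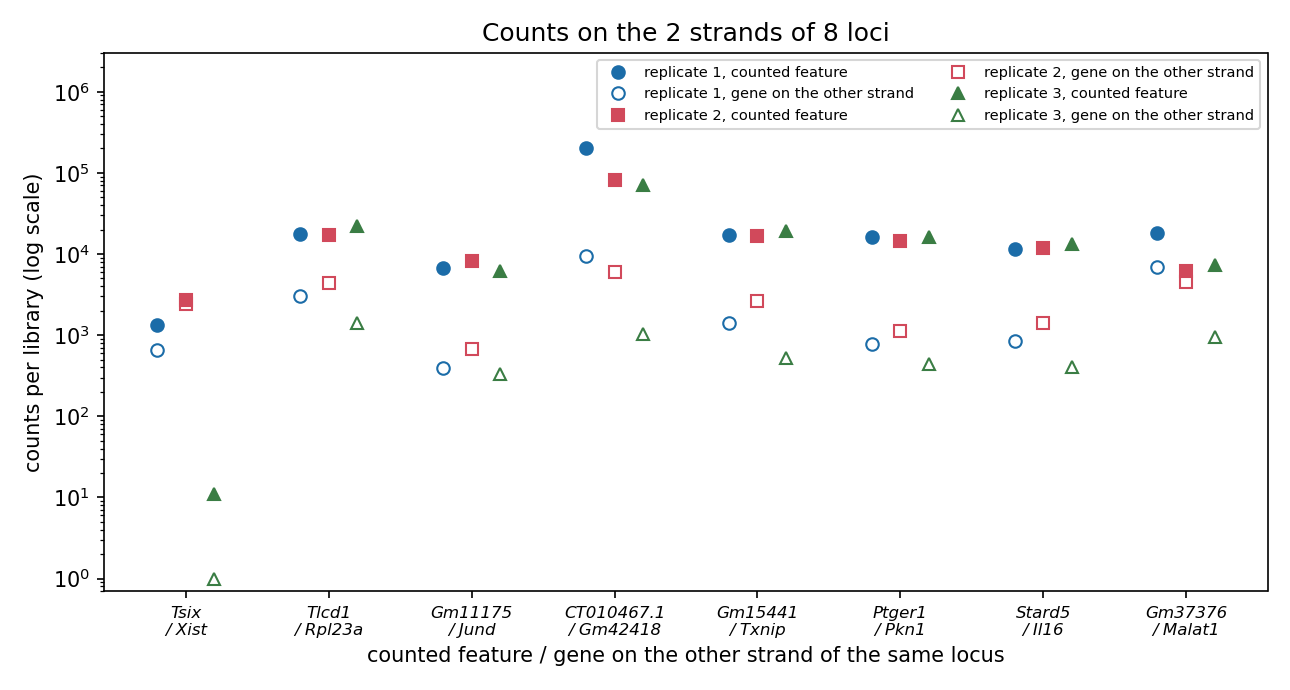
Counts per library (log scale) of 8 features (filled symbols) and of the gene on the other strand of the same locus (open symbols), with circles, squares and triangles for replicates 1, 2 and 3. In each library every counted feature lies above its partner, for example 17080, 16563 and 19015 counts of Gm15441 against 1393, 2614 and 520 of Txnip.

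The first question was which T cell transcripts these libraries held. Transcripts of T cell identity and of naive T cells were abundant, and 11 of the 30 Th1 program genes had at most 3 counts over the 3 libraries. Cd4, the co-receptor of helper T cells (chromosome 6, 124864692 to 124888221), stood at 236 ± 122.9 TPM (n = 3) with 1849, 2807 and 662 counts. Tcf7, a transcription factor of naive and memory T cells (chromosome 11, 52252371 to 52283014), stood at 619 ± 332 TPM. Tbx21, the master regulator T-bet of Th1 cells (chromosome 11, 97098071 to 97115331), had 1, 3 and 0 counts, and Ifng, the defining Th1 cytokine (chromosome 10, 118441046 to 118445892), also had 1, 3 and 0 counts.

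All 20 T cell identity genes reached 1 TPM in all 3 libraries. The T cell receptor constant genes led the list, with Trbc2 at 610 ± 401, Trac at 576 ± 377 and Trbc1 at 476 ± 300 TPM, followed by the kinase gene Lck at 331 ± 169 TPM. Cd3e, a chain of the receptor's CD3 complex, stood at 85.8 ± 48.3 TPM, and its exons overlap those of Gm48719. The median member of the list lay at the 100 percentile of 10000 random lists of the same size. All 12 naive T markers also reached 1 TPM in all 3 libraries and lay at the 100 percentile. After Tcf7 the highest were Il7r, the interleukin 7 receptor, at 205 ± 107 TPM, and Ccr7, a chemokine receptor of lymph node homing, at 203 ± 124 TPM. Other members included Klf2 at 121 ± 62.7 and Foxp1 at 22.3 ± 12.4 TPM.

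Of the 30 Th1 program genes, 12 reached 1 TPM in all 3 libraries. The highest were Irf1, an interferon-induced transcription factor gene whose exons overlap Gm17334, at 87.3 ± 35.7 TPM, the protease gene Ctsw at 82.4 ± 38.2 TPM, the interleukin 18 receptor gene Il18r1 at 28.4 ± 18.7 TPM and Id2 at 23.9 ± 17.1 TPM. Stat4, which transmits interleukin 12 signals, stood at 14.8 ± 7.15 TPM. The chemokine receptor gene Cxcr3 had 0 counts in all 3 libraries, where 3 counts would be 0.921, 0.885 and 1.16 TPM in replicates 1, 2 and 3. This floor covers counting error on the counted strand only and does not bound the transcript's abundance. Gzmb, which encodes granzyme B, had 2 counts in all, and Tnf had 28, 36 and 7 counts. The list's median lay at the 0 percentile of random lists of expressed or listed protein-coding genes, and over the 25 members without exon overlap at the 0.03 percentile. Against all annotated protein-coding genes, silent ones included, it lay at the 51.96 percentile.

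**Figure D2:**
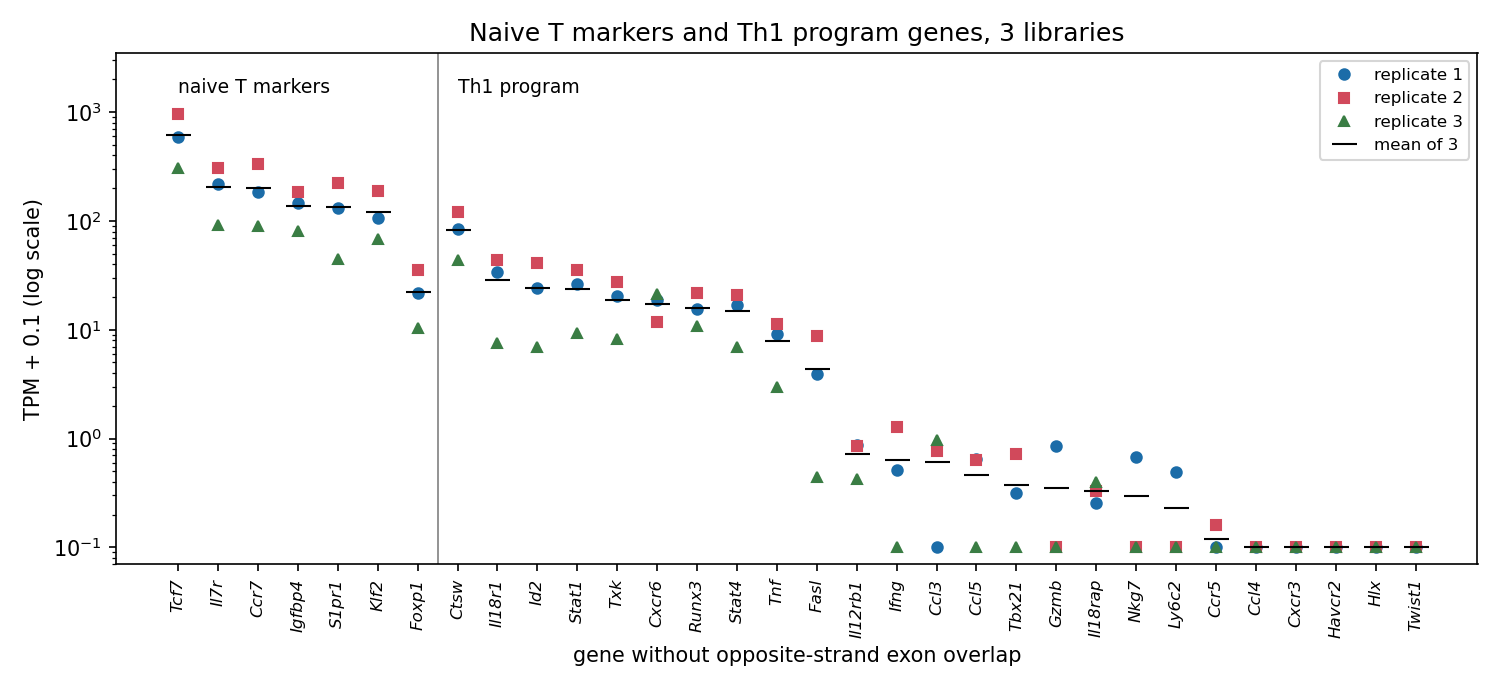
TPM plus 0.1 on a log scale for 7 of the 8 naive T markers and 25 Th1 program genes without opposite-strand exon overlap. Circles, squares and triangles are replicates 1, 2 and 3, and the dash is the mean TPM plus 0.1. Tcf7 is highest at 619 TPM, and Cxcr3 has no counts in any library.

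Markers of other cell types had low medians, with single members higher. The medians of the NK, B cell, myeloid, erythroid and platelet, and stromal and epithelial lists lay at the 0 percentile, and that of the dendritic cell and MHC class II list at the 0.07 percentile. Against all annotated protein-coding genes these 6 lists lay between the 10.9 and 36.4 percentile, inside the central 95%. Cd8a, the co-receptor of cytotoxic T cells, had 0, 1 and 0 counts and Cd8b1 27, 53 and 17. Among B cell markers Igkc had 0 counts, while Ighm stood at 221 ± 140 TPM and Cd79a at 43.7 ± 9.14 TPM. Lyz2, a lysozyme of myeloid cells, had 1 count in all, and Csf1r stood at 81.1 ± 14.5 TPM with exons that overlap Hmgxb3 on the other strand. Ncr1, an NK cell receptor gene, had 1 count, against 12.1 ± 7.20 TPM for the perforin gene Prf1. Cd74, Col1a1 and Hba-a1 had 20, 2 and 0 counts in all, and Pecam1 stood at 46.4 ± 24.4 TPM. Of the gamma-delta and innate-like markers, Trdc stood at 3.15 ± 1.15 TPM with exon overlap and Tcrg-C1 had 1 count.

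Cytokine genes lay at the 0 percentile as a list of 32 members, and at 43.76 against all annotated protein-coding genes. Il2, the T cell growth factor, had 1 count in each library, Il21 had 4, 7 and 6 counts with exon overlap, Il5, also with exon overlap, had 2, 0 and 3, and Il17f had 1, 3 and 0. Il10, Il17a and Il22 had 0 counts in all 3 libraries. Ltb, which encodes lymphotoxin beta, was the highest cytokine gene at 230 ± 121 TPM, followed by Cd40lg at 75.8 ± 43.8 TPM. Cytokine receptor genes as a list lay at the 99.67 percentile (97.1 on TMM-scaled CPM, which have no length correction, inside the central 95%), with Il27ra (exon overlap of 2 bases with Palm3) at 110 ± 59.2 and Il21r at 92.9 ± 36.2 TPM behind Il7r. Chemokine receptors lay at the 0 percentile, with Ccr1 at 0 counts, although Ccr7 and Cxcr4 (39.7 ± 16.2 TPM) were present. Cytotoxic effectors lay at the 0.02 and inhibitory receptors at the 0.78 percentile. Against all annotated protein-coding genes chemokine receptors, cytotoxic effectors and inhibitory receptors lay at 38.9, 48.16 and 54.37. Gzma had 0, 2 and 0 counts and Pdcd1, which encodes PD-1, had 7, 10 and 0.

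Of the other lists, interferon response genes lay at the 99.94 percentile, with Psmb9 at 130 ± 10.4 and Psmb8 at 88.6 ± 47.9 TPM, both with exon overlap, and Igtp at 79.7 ± 45.8 TPM without. Over the 17 members without exon overlap this list lay at the 92.4 percentile. Oxidative phosphorylation genes lay at the 99.92 percentile, led by Atp5a1 at 119 ± 75.1 TPM, and on TMM-scaled CPM at 96.99, inside the central 95%. Stress response genes lay at the 98.83 percentile, led by Atf4 at 106 ± 49.0 TPM, and inside the central 95% without replicate 1 (96.99), without replicate 3 (97.03) and on TMM-scaled CPM (95.22). Ribosomal proteins and common reference genes lay at the 100 percentile, the latter led by Eef1a1 at 3516 ± 1887 and B2m at 1948 ± 1117 TPM. Glycolysis genes lay at the 91.9 percentile (97.86 on TMM-scaled CPM, above the central 95%) with Ldha at 99.1 ± 50.4 TPM, sterol and fatty acid synthesis at the 64.0 percentile with Mvd at 99.8 ± 9.05 TPM, and activation genes at the 45.6 percentile with Junb (exon overlap with Prdx2) at 95.5 ± 25.2 TPM and Cd69 at 12.2 ± 6.998 TPM. G1/S genes lay at the 77.8 percentile and G2/M genes at the 0.04 percentile (42.91 against all annotated protein-coding genes). The proliferation marker Mki67 stood at 5.56 ± 1.25 TPM and Top2a at 1.25 ± 0.448 TPM. The highest genes of the G1/S and G2/M lists, Gins2 at 431 ± 91.9 TPM and Kif20a at 119 ± 33.5 TPM, have exons that overlap Gse1 and Cdc23 on the other strand.

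The highest protein-coding genes outside the mitochondrial and ribosomal protein genes were Gm20721 at 5702 ± 1330 TPM, Gm17606 at 3809 ± 867, Eef1a1, G530012D18Rik at 3287 ± 462, Gm26602 at 2619 ± 530, Gm17617 at 2495 ± 479, the actin-binding thymosin genes Tmsb10 at 2461 ± 640 and Tmsb4x at 2304 ± 1137, Tlcd1 at 2186 ± 651, and B2m. Of these 10 genes, Gm20721, Gm17606, G530012D18Rik, Gm26602, Gm17617 and Tlcd1 have exons that overlap Gnas, Acin1, Sp110, R3hdm4, Zfp346 and Rpl23a on the other strand. In all, 11812 genes reached 1 TPM in all 3 libraries, of which 9043 were protein coding, and 5946 of those had no such overlap. Of the 31 lists examined, 8 lay above the central 95% of the random lists and 14 below it. Against all annotated protein-coding genes 11 lay above, with G1/S, glycolysis and sterol and fatty acid synthesis added, and 0 below, and without genes of exon overlap 6 of 29 lay above and 17 below. Th2, regulatory T and follicular helper programs lay inside the central 95%, at the 14.3, 23.9 and 17.9 percentile, and the Th17 program below it, at 0.04. Without genes of exon overlap the Th2 program lay below it, at 0.61, and against all annotated protein-coding genes the Th17 program lay inside it, at 42.36.

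The Th1 program was then compared with the programs of the other helper subsets, to ask which subset's transcripts were higher. No contrast passed the test. The mean log2(TPM + 0.1) of the Th1 program was 0.53, against 1.15 for the Th2 program, −0.97 for the Th17 program, 1.83 for the regulatory T program and 1.44 for the follicular helper program. The Th1 program minus Th2 difference was −0.62 ± 0.30 (SD, n = 3 libraries, adjusted p = 0.553, permutation test of the gene labels). The other differences were 1.495 ± 0.40 against Th17 (adjusted p = 0.448, permutation test), −1.30 ± 0.15 against regulatory T (adjusted p = 0.448, permutation test) and −0.91 ± 0.18 against follicular helper genes (adjusted p = 0.553, permutation test). Each kept its sign in all 3 libraries. The tests ran over 30 against 11 to 15 genes, which are not independent replicates. Without genes of exon overlap the Th2 difference was 0.16, and with only members of at least 1 TPM in a library the differences from Th2, regulatory T and follicular helper genes were 0.84, 0.021 and 0.67, all without passing the test.

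Among the members of these programs, Gata3, the Th2 regulator, stood at 15.1 ± 6.00 TPM with exons that overlap Gm13256. Stat6 (70.1 ± 26.1 TPM) and Il4ra (58.0 ± 26.1 TPM) were the highest Th2 genes, and both have exon overlap. Il4 had 22, 18 and 27 counts and Il13 had 1. In the Th17 list Batf (37.3 ± 9.28 TPM) and Stat3 (26.0 ± 13.0 TPM, with exon overlap) led. Foxp3, the regulatory T regulator (X chromosome, 7579676 to 7595243, plus strand), had 1003, 935 and 1203 counts and shares 590 exonic bases with Ccdc22 on the minus strand. Other regulatory T genes were lower, with Izumo1r at 38.6 ± 8.65, Tnfrsf18 (exon overlap) at 18.3 ± 9.77, Ctla4 at 3.99 ± 3.31 and Il2ra at 2.85 ± 1.77 TPM. Of the follicular helper genes, Bcl6 stood at 3.50 ± 1.94 TPM with exon overlap, Btla at 40.5 ± 21.1 and Slamf6 at 23.3 ± 11.4 TPM.

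A contrast added after the data were seen set the Th1 program against the naive T markers. The Th1 program was lower by a mean of −5.80 ± 0.24 on the log2 scale (SD, n = 3 libraries, lower in all 3). A permutation test of the gene labels gave p = 1e-05, the smallest that 100000 resamples can give. It ran over 30 against 12 genes, which are not independent replicates. Because the contrast was chosen after the data were seen, this p adds no support. Over members without exon overlap, 25 against 8 genes, the difference was −6.89 ± 0.34.

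Gene pairs were compared within each library to ask which partner of opposing fates was higher. The first gene of the pair was higher in all 3 libraries in 4 of 18 pairs, the second in 7, and no direction was given for 7 pairs. A direction required at least 3 counts of the higher gene in each library, a rule added after the ratios were seen, and with every ratio at the floor counted the first gene was higher in 8 pairs. In 16 pairs a gene had under 3 counts in a library. Cd4 exceeded Cd8a, with 5318 counts against 1 over the 3 libraries, a ratio per base of 4797 (95% exact binomial interval 861 to 189507). Il18r1 was at least 123.1-fold higher than the Th2 receptor gene Il1rl1, which had 0 counts and was set at 3 counts in each library. Il12rb2, whose exons overlap Serbp1 on the other strand, exceeded Il12rb1 by a ratio of 21.9 (interval 12.9 to 40.7). The log2 count ratio of replicate 3 to 2 was 0.20 for Il12rb2. Its median was −0.52 over tested genes with exon overlap and 0.12 over nested features. Whether the Il12rb2 counts come from its locus was not tested, so the ratio may not compare Il12rb2 transcripts with those of Il12rb1.

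In the other direction, Gata3 exceeded Tbx21 by a ratio of 51.8 (interval 20.02 to 191), Foxp3 exceeded Tbx21 by 490 (interval 191 to 1799), Bcl6 exceeded Tbx21 by 12.2 (interval 4.64 to 45.3) and Il4 exceeded Ifng by 17.7 (interval 6.59 to 66.8). Il4 lies within 5 kb of an opposite-strand gene, and its log2 count ratio of replicate 3 to 2 was 0.57, against a median of −1.82 over tested genes of that class. Prf1 exceeded Gzmb by 48.0 (interval 13.1 to 400). Stat4 was below Stat6 by a mean log2 ratio of −2.31 ± 0.34, and Runx3, a transcription factor of the cytotoxic lineage, was below Zbtb7b, which encodes the CD4 lineage factor ThPOK, by −1.71 ± 0.11 (n = 3). Stat6 and Zbtb7b have exon overlap, as do Foxp3, Gata3 and Bcl6. The log2 count ratio of replicate 3 to 2 was 0.36 for Foxp3. The median was −0.52 over tested genes with exon overlap and 0.12 over nested features. Ccdc22, on the other strand, had 40, 52 and 32 counts. Whether the Foxp3 counts come from its locus was not tested, so the ratio may not compare Foxp3 transcripts with those of Tbx21. Ratios of Ifng to Il13, Il17a and Il10, and of Cxcr3 to Ccr4 and Ccr6 rested on too few counts to give a direction in all 3 libraries. Eomes, with exon overlap, had 4, 12 and 14 counts, and its ratio to Tbx21 differed in sign between libraries, with Tbx21 at or under 3 counts in each. The exact sign-flip permutation test over 3 libraries cannot go below p = 0.25, so no pair could pass it. Neither gene has exon overlap in 9 of the 18 pairs, and of these the first was higher in 2 and the second in 2.

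The libraries were next compared with each other. Replicate 3 had fewer counts of most genes away from other annotations, and similar counts of features nested in exons of the other strand. Over 2603 genes with no opposite-strand gene within 5 kb, the median log2 count ratio of replicate 3 to replicate 2 was −2.06, and over 161 features nested in exons of the other strand it was 0.12. Cd4 had 662 counts in replicate 3 and 2807 in replicate 2, whereas Foxp3 had 1203 and 935. Relative to counting error, 6649 of 10662 tested genes varied between the libraries (Poisson homogeneity test, Benjamini-Hochberg adjusted p under 0.05), and 4213 differed by over 1 on the log2 scale between their highest and lowest library. The common biological coefficient of variation from edgeR was 0.374. Over genes with no opposite-strand gene within 5 kb, 783 of 2721 varied and 478 differed by over 1, with a coefficient of 0.221. Without replicate 3, 3303 genes varied and 515 differed by over 1, and without replicate 2, 2161 differed by over 1.

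**Figure D3:**
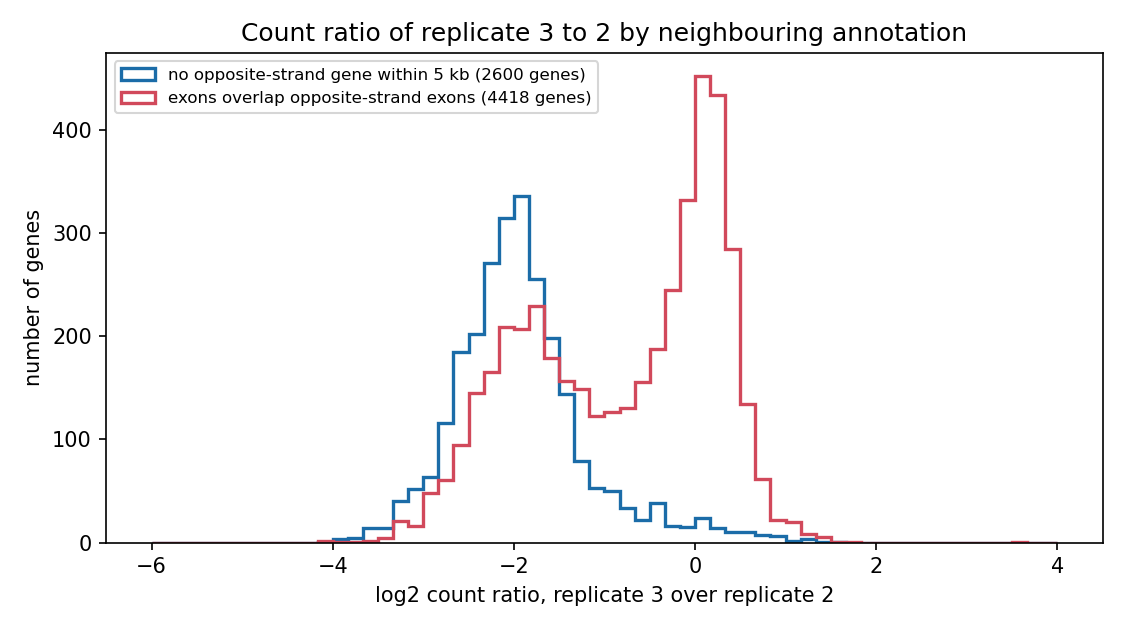
Number of genes by log2 count ratio of replicate 3 over replicate 2, for 2600 tested genes with no opposite-strand gene within 5 kb and 4418 tested genes whose exons overlap opposite-strand exons. The first class has its median at −1.99 and the second at −0.52, with a peak near 0 in the second class only.

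The 10 genes of largest range among those past the threshold with a mean of at least 10 CPM were Tsix, Gm20481, Gm15247, Gm15726, Gm18009, Hspa1b, Gm37520, G530011O06Rik, Cfap45 and Gm44573. Tsix, which lies opposite Xist, had 1351, 2746 and 11 counts (log2 range 6.30), and Gm20481, opposite the heat shock gene Hspa1a, had 557, 28 and 351 (range 5.06). Hspa1b, a stress-induced chaperone gene with no opposite-strand neighbour, had 180, 20 and 60 counts (range 3.50), and Hspa1a had 58, 4 and 15. Gm15247, Gm15726 and G530011O06Rik lie opposite Mid1 and were highest in replicate 3, with 265, 918 and 157 counts against 16, 81 and 35 in replicate 1. The sex-linked list varied as well. Xist, the X-inactivation transcript, had 665, 2393 and 1 counts, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 396, 4 and 185.

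Gene lists shifted between libraries relative to random lists of matched expression, which were not matched on exon overlap. Of 60 list and library values, 22 lay outside the central 95% of 10000 random lists, where 5% of the values would be 3. T cell identity genes had a median shift of 0.05, 0.24 and −0.31 in replicates 1, 2 and 3, and naive T markers of 0.05, 0.25 and −0.30, all outside that range. Cytokine receptors, ribosomal proteins and common reference genes also lay outside it in all 3 libraries, in the same directions. Mitochondrial genes and cytotoxic effectors lay below it in replicate 3. Over genes without exon overlap 5 of 54 values lay outside, against 2.7 for 5%. These were the Th1 program in replicate 1 (0.19), cytotoxic effectors in replicates 2 and 3 (0.39 and −0.81) and mitochondrial genes in replicates 1 and 3 (0.24 and −0.47). In the cytotoxic list Fasl had 14, 33 and 1 counts and Serpinb9 had 17, 43 and 2.

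The assay was labelled total RNA while the name of the linked library document refers to poly(A)+ RNA, so transcripts with and without a poly(A) tail were measured. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were low, with 0.0130% ± 0.0025 of TPM over 67 genes, of which 46 had at most 3 counts over the 3 libraries. The polyadenylated histone variants held 0.0223% ± 0.0127 over 7 genes, with H3f3b at 102 ± 66.0 and H3f3a (exon overlap) at 15.4 ± 5.69 TPM. As lists, the levels lay at the 0 percentile for replication-dependent histones, 3.91 for RNAs without a canonical tail and 8.31 for mitochondrial genes. The mitochondrial list held 37 genes, tRNA genes included, and was set against protein-coding genes. Of its members, 17 had at most 3 counts over the 3 libraries, so its median does not describe the mitochondrial protein genes. The mitochondrial value was 99.93 without replicate 2, 0.2 without replicate 3 and 0.06 without genes of exon overlap, and that of RNAs without a canonical tail was 2.03 without replicate 1 and 0.11 without genes of exon overlap. Against all annotated protein-coding genes the histones lay at 23.76. Of RNAs without a canonical tail, Rn7sk had 118, 19 and 9 counts, Rmrp, with exon overlap, 4, 1 and 1, and Rn7s1 and Rn7s2 had 0 counts, while Malat1 stood at 316 ± 219 TPM with exons that overlap Gm37376. Protein-coding genes held 43.5% ± 9.24 of TPM and lncRNA genes 40.1% ± 8.22, and by share of counts 71.2% and 23.3%. Without genes of exon overlap the shares of TPM were 75.3% and 6.19%. Mitochondrial genes held 3.60% ± 0.18 and ribosomal protein genes 6.42% ± 2.57 of TPM. Most of the mitochondrial share came from mt-Nd6 alone, at 20667, 20054 and 27128 TPM in replicates 1, 2 and 3. The heavy-strand gene mt-Co1 stood at 3100, 4865 and 986 TPM. In the mitochondrial genome mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l had 0 counts in all 3 libraries. These genes lie in 1 stretch (7013 to 10173), and fragments that map to more than 1 place were not counted. Their 0 counts may come from the counting and do not show absent transcripts, and the cause was not tested. The genes mt-Rnr1 and mt-Rnr2 stood at 138 ± 87.2 and 133 ± 77.4 TPM.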

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

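All tests in this part were chosen after the data were seen, and their bounds were written after a first run of the tests. Identifiers with no name in the annotation used here entered no gene list, gene pair or transcript class, although they were part of the totals, the strand classes and the tests between libraries. They held 25322, 13021 and 13353 counts in replicates 1, 2 and 3, above the 3 counts that a count of 0 allows. The largest, ENSMUSG00000092267.1 on chromosome 19 (5797562 to 5798549, plus strand), held 18171, 5800 and 6283 counts, with all of its 425 exonic bases opposite exons of Malat1.

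Features opposite abundant genes held most of the counts of these libraries. An unstranded library or genomic DNA would give both strands the same density, and the host gene's median density was at most 5.55% of the nested feature's in the 3 libraries. Antisense transcription would not follow the host's exons, and features opposite exons exceeded their hosts' density more often than features opposite introns, by at least 49.2 percentage points (182 and 1102 features). What stays open is that the counting strand may have been opposite to that of the library, which needs the same difference between exons and introns, and the library kit is not given in the sources used here. The higher density of nested features (76.0% of 204 denser in all 3 libraries, a median ratio of 18.03 or more in each) was first run as a test of this, but it is the pattern itself and adds no support.

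Most genes had fewer counts in replicate 3. Sequencing depth alone would move nested features and genes with no opposite-strand neighbour alike, and their median log2 count ratios of replicate 3 to 2 differed by 2.17. Whether the share of fragments on the counted strand differs between libraries stays open. The fall of hosts relative to nested features was first run as a test of it, but that restates the values reported for these classes. No biological explanation was tested, as the design holds 1 group.

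Naive T cell transcripts exceeded Th1 effector transcripts in cells labelled T-helper 1. The counted strand hiding Th1 transcripts was tested by asking whether both lists lay near the floor. Naive markers without exon overlap, on the same strand, had a median of 169 TPM. The Th1 program had 1.87, with members under 3 counts set at 3. This cannot decide the question. A loss shared by all genes would leave abundant transcripts above the floor and low ones under it. Whether low Th1 transcripts such as Tbx21 and Ifng were lost in this way stays open. Another cell type in place of CD4 T cells would bring its own transcripts. Over members without exon overlap, the highest median of 6 lists of other cell types was 0.284 TPM, against 236 TPM for Cd4. Most members of these lists were thus low, but single members stood higher, as reported above. A median set by low members cannot exclude a minor share of other cells. The CD8 and gamma-delta lists were not among the 6. Whether the cells were taken before differentiation, as the 0 hours of the file headers could mean, stays open. The ratio of naive markers to Th1 genes was first run as a test of it, but that is the pattern itself, and the 0 hours could also count from another start.

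A further test, of mt-Nd6 against the heavy-strand protein genes with counts, was run after the values were seen and is given as values only. The density of mt-Nd6 was 18.4, 12.2 and 106 times the median of 6 such genes in replicates 1, 2 and 3.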

How the results depend on the processing

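Alternatives that leave out genes by their opposite-strand neighbours, and the rule for the direction of a pair, were chosen after the data were seen. With every ratio at the floor counted as a direction, as first computed, 8 of 18 pairs had the first gene higher, in place of 4. Restricting to genes without opposite-strand exon overlap gave 7201 detected genes, 2 of 9 pairs with the first gene higher, 2274 genes varying, 1479 with a range over 1, 5 list shifts outside the central 95%, TPM shares of 75.3% protein coding and 6.19% lncRNA, and a Th1 minus Th2 difference of 0.16. Fewer genes are tested there. Restricting to genes with no opposite-strand gene within 5 kb gave 783 and 478 genes. With only members of at least 1 TPM in a library, the Th1 program minus Th2, regulatory T and follicular helper differences turned to 0.84, 0.021 and 0.67, since members under 1 TPM in all 3 libraries are left out. No contrast passed the test under any alternative (adjusted permutation p from 0.336 to 0.98). A threshold of 5 TPM gave 7483 detected genes, no filter beyond a count above 0 gave 9759 genes with a range over 1 among 19958, and the share of counts was 71.2% protein coding and 23.3% lncRNA. The lists below the central 95% depend on the background, with 14 of 31 below it against expressed or listed genes and 0 against all annotated protein-coding genes, which include silent ones. On TMM-scaled CPM in place of TPM, which changes the scaling and drops the length correction together, cytokine receptors (97.1), oxidative phosphorylation (96.99) and stress response (95.22) were no longer above it, and glycolysis (97.86) was, with the cause not tested. Under this setting 16 lists lay below the central 95%, with RNAs without a canonical tail (0.02) and mitochondrial genes (0) added. Leaving out each replicate gave 3303 to 6377 varying genes and 515 to 3806 genes with a range over 1, the lowest of both without replicate 3 (2161 genes with a range over 1 without replicate 2), and the cause was not tested. Of the remaining values under alternatives of the same main results, 67 planned and 4 added ones stayed within the spread, within 1.5 times or on the same side of the threshold. Posterior mean TPM was not run, since the tables hold counts. No paired analysis was possible because the series has a single group. With 3 counts as the floor, genes such as Tbx21 and Ifng were at the limit of depth.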

Other observations

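The tests in this part were chosen after the data were seen. The 2 shares of sex-linked counts were first run as tests of an explanation and are given here as values only. Sex-linked transcripts differed between the 3 libraries although the labels give a shared donor identifier and no sex. Xist had 2393 counts in replicate 2, where the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 4. Replicate 3 had 1 count of Xist and 185 of the Y-linked genes. Replicate 1 had 665 counts of Xist and 396 of the Y-linked genes. Relative to the TMM-scaled counts of genes with no opposite-strand neighbour, Xist of replicate 1 was 43.9% of that of replicate 2, and the Y-linked genes of replicate 1 were 82.8% of those of replicate 3.

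The stress response list did not shift in any library, with medians of −0.01, 0.01 and 0.04 inside the range of random lists, while single members varied. Hspa1b, on chromosome 17 (34956436 to 34959238), had 180 and 60 counts in replicates 1 and 3 and 20 in replicate 2, and Gm20481 opposite Hspa1a had 557 and 351 against 28. The stress genes Atf4 and Ddit4 did not share this order, as Atf4 had 331, 531 and 153 counts and Ddit4 had 306, 494 and 132 in replicates 1, 2 and 3.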
